A study of Mus musculus with 4 samples.

How the data were processed

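Total RNA of 4T1 cells was extracted with TRIzol and 1.3 ug was made into libraries by an Illumina protocol, per the labels' protocols. The labels name 2 WT and 2 DHODH KO samples, and each column of the table was matched to its sample by name. The values are FPKM as deposited, reads scaled to the length of the gene and to the reads of the library. Per the submitters' processing notes, fastp and HTSeq were used with the genome build GRCm39, without versions. The aligner, the gene annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

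The table held 16695 genes, and Entrez identifiers of 16580 (99.3%) matched the GRCm38.p6 RefSeq gene table, used only for gene type. As that build differs from the authors', no coordinates are given. Of the genes, 98.4% were protein coding. The table may hold only part of the genes measured, and mitochondrially encoded genes were not analysed here.

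FPKM values of a gene fall on whole multiples of the value of 1 read. Searching up to 20000 reads per value with a tolerance of 0.002 of a read recovered whole reads for 16515 genes (98.9%), and the 180 others, mostly of high expression, were left out of the read sums. The report gives the sums per library. The relative depth, estimated apart from those sums from the value of 1 read in each library, was 1.00, 0.980, 1.07 and 1.07 against WT replicate 1. Sums of FPKM lay between 391546.4 and 399199.8, and the 10 highest genes held 8.91% to 9.19% of them. On the recovered reads, replicates differed by more than counting noise, with a mean chi-square per gene of 3.76 over 11644 genes in WT and 6.38 over 11892 genes in KO, among genes with at least 20 reads over both libraries. This cannot show that replicates came from separate cultures. They were kept as separate samples, as the labels name them. Pearson's r across genes of log2(FPKM + 1) was 0.997 between the WT and 0.994 between the KO libraries, across genes that are not independent replicates.

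Genes with a mean FPKM of at least 1 over the 4 samples (10170) were tested with limma-trend on log2(FPKM + 1), KO against WT, two-sided, without covariates, and called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold (limma 3.58.1, R 4.3.3). Moderation added 5.15 prior degrees of freedom. Fold changes given as folds are ratios of mean FPKM. Of 35 gene lists, 32 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, adjusted over the lists. With the correlation estimated from the data, none of the lists passed, and the smallest adjusted p was 0.405. Lists with unadjusted p-values of this test from 0.0481 to 0.114 share that adjusted p, so it does not rank them. The correlation was estimated from 2 libraries per group and is itself uncertain. The lists that had too few tested members were mitochondrially encoded genes, immune cell markers, and fibroblast and endothelial markers. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used for tables and figures.

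The tests, lists and alternatives were fixed before the data were examined, apart from those named as added. The genes named were Dhodh, the 12 called genes with the largest increase and the 12 with the largest decrease whose values did not overlap between groups, with a mean of at least 5 FPKM in the higher group and without predicted genes or pseudogenes, and up to 4 members with the smallest adjusted p of each list past the threshold and of the 4 pyrimidine lists. A gene that this rule takes is not reported here. The sizes of genes with close copies are uncertain where reads could be divided among them.

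The test was checked on simulated data for the KO against WT comparison over 10170 genes. It called 50% of genes changed by 0.25 on the log2 scale, 96% of those changed by 0.5 and 100% of those changed by 1 or 2, with 17 unchanged genes called beside 200 changed ones. With no change simulated it called 5 genes and 0 lists, and 1 list raised by 0.3 was called. Noise was drawn for each gene on its own, so these data held no correlation between genes. The check therefore cannot judge the preset correlation of the list test. As only 200 genes were changed, the shares called need not hold for the real data, where 64.7% of genes were called.

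The alternatives were another pseudocount, filter, scaling, variance model or fold threshold, a replicate block, leaving out each library, and other list tests. The alternatives planned for a table of counts were not run, as the values are FPKM. Added after seeing the data were voom on recovered reads, camera over 302 pathways of the authors' annotation column with 10 to 300 tested genes, marker lists of heart muscle, skeletal muscle, kidney, liver, hair follicle, testis, blood, brain and macrophages, and 10000 random lists matched on gene length and mean expression.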

Results

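RNA-seq was used to profile 4T1 cells, a mouse breast cancer cell line, either wild type (WT) or knocked out for Dhodh (DHODH KO). DHODH, dihydroorotate dehydrogenase, is the enzyme of the inner mitochondrial membrane that oxidises dihydroorotate to orotate in de novo pyrimidine synthesis and passes the electrons to ubiquinone. Each group held 2 libraries, and the question was how gene expression differs between the genotypes. The table gave FPKM for 16695 genes. Whole reads recovered from the FPKM steps summed to 25750573 reads in WT replicate 1, 25201213 in WT replicate 2, 28133343 in DHODH KO replicate 1 and 28079208 in DHODH KO replicate 2. The labels do not say whether libraries of a genotype came from separate cultures or whether the KO cells were a clone, so p-values measure only the spread between these libraries. Values are mean FPKM ± SD (n = 2 per genotype), and log2 fold changes are KO minus WT ± SE on the log2(FPKM + 1) scale, which understates the change of low genes. Adjusted p-values of genes are Benjamini-Hochberg values from limma-trend, and those of gene lists are from camera.

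Dhodh RNA (Entrez Gene 56749) was still present in the KO cells and only slightly lower than in WT. It measured 10.87 and 10.33 FPKM in WT replicates 1 and 2, and 9.67 and 8.69 FPKM in DHODH KO replicates 1 and 2. The mean was 10.6 ± 0.377 FPKM in WT and 9.18 ± 0.694 FPKM in KO, a log2 fold change of -0.19 ± 0.068 with an adjusted p of 0.0425. A value summed over the gene cannot show a small insertion or deletion, so it tests the labels only weakly. The call was lost without WT replicate 1 (log2 fold change -0.16, adjusted p = 0.170), without WT replicate 2 (-0.22, adjusted p = 0.0597) and without DHODH KO replicate 2 (-0.12, adjusted p = 0.200). It was also lost with no filter on low values (adjusted p = 0.119), after rescaling to TPM (0.0540), without the limma trend (0.0535), with voom on the recovered reads (0.0531) and when a log2 fold change of at least 1 was asked for, while over all settings the adjusted p ran from 0.0153 to 0.200.

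**Figure D1:**
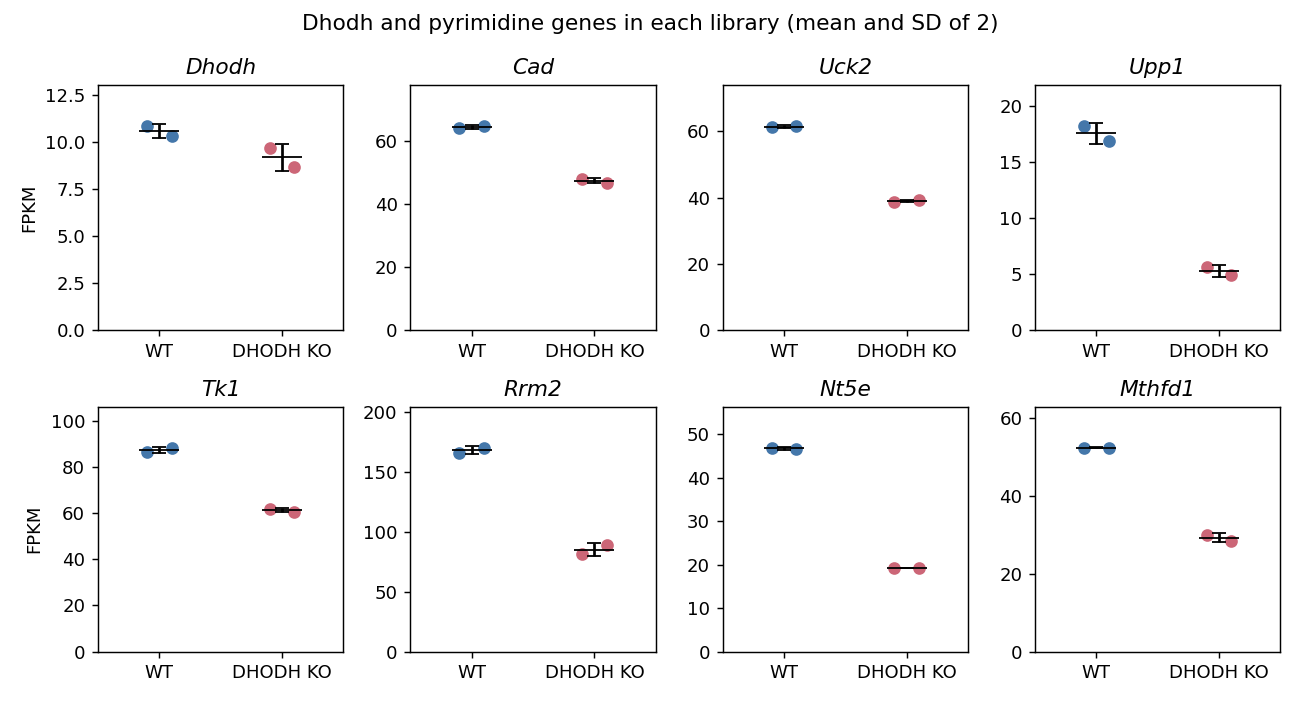
FPKM of Dhodh and 7 other pyrimidine or deoxynucleotide genes in each library, with WT in blue, DHODH KO in red, and the black bar and whiskers giving the mean and SD of 2 libraries. Dhodh fell from 10.6 to 9.18 FPKM, whereas Upp1 fell from 17.5 to 5.29 FPKM and Rrm2 from 168 to 85.1 FPKM. Each gene drawn fell, and members of the same lists that rose, such as Cda, Tk2 and Dck, are not shown.

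The largest increases in KO on the log2(FPKM + 1) scale, by a rule fixed beforehand, were in Gpnmb, Cxcl2 and Icam1. Gpnmb, a lysosome-associated membrane glycoprotein, rose from 1.26 ± 0.146 to 28.4 ± 0.242 FPKM, 22.5-fold. The neutrophil-attracting chemokine gene Cxcl2 rose 21.3-fold to 28.7 ± 2.53 FPKM, and the adhesion molecule gene Icam1 rose 10.8-fold to 37.0 ± 0.327 FPKM. Ccl20, another chemokine gene, rose 7.01-fold, and Ddit3, which encodes the stress transcription factor CHOP, rose 7.19-fold to 33.6 ± 0.181 FPKM. The lysosomal genes Cd68 and Hexa rose 6.31-fold and 6.76-fold, to 90.6 ± 1.57 and 40.8 ± 0.103 FPKM. Ephx1, an epoxide hydrolase gene, rose 7.495-fold, and Adm, which encodes the vasodilator peptide adrenomedullin, rose 28.9-fold from 0.195 ± 0.0752 to 5.65 ± 1.12 FPKM. Tmie and Lrrn4cl rose 7.44-fold and 5.95-fold. For all of these genes the log2 fold changes lay between 2.30 and 3.70 and the adjusted p-values between 3.1e-07 and 8.5e-06. Mb, the myoglobin gene, was also among the 12 largest increases, but its KO libraries differed widely, at 2.01 FPKM in DHODH KO replicate 1 and 29.7 FPKM in DHODH KO replicate 2 (log2 fold change 3.02 ± 0.895, adjusted p = 0.0204; 4.69 without the former and 1.34 without the latter). DHODH KO replicate 2 also held transcripts of heart muscle marker genes. Over a list without Mb they summed to 93.9 FPKM, against at most 0.153 FPKM in the other libraries. Mb fell below the expression filter without DHODH KO replicate 2, and its call was lost with robust limma (adjusted p = 0.240), without the trend (0.0527) and with no filter (0.165), over a range of 1.2e-06 to 0.240 in all settings.

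The largest decreases in KO on the log2(FPKM + 1) scale, by the same rule, were in Oas1a, H4c9 and Anxa8. Oas1a, an interferon-induced oligoadenylate synthetase gene, fell from 12.1 ± 0.545 to 0.545 ± 0.539 FPKM and was 22.3-fold higher in WT (13.1-fold without DHODH KO replicate 1 and 74.2-fold without DHODH KO replicate 2). Oasl1 and Ifit1, also interferon-induced, were 3.89-fold and 6.80-fold higher in WT. H4c9, a replication-dependent histone gene, fell from 23.2 ± 3.28 to 2.54 ± 0.327 FPKM. Anxa8 was 14.6-fold higher in WT, Ctsw, a cathepsin gene, 14.9-fold, and Ggct, an enzyme gene of glutathione breakdown, 9.10-fold. The kallikrein protease gene Klk10 fell from 26.3 ± 2.11 to 4.26 ± 0.483 FPKM, and the matrix metalloprotease gene Mmp10 from 9.23 ± 0.196 to 1.76 ± 0.261 FPKM. Dynap, the endothelial lipase gene Lipg and the immune checkpoint receptor gene Tigit were 5.15-fold, 6.14-fold and 5.25-fold higher in WT. The log2 fold changes of these 12 genes lay between -3.13 and -1.84, with adjusted p-values between 1.5e-06 and 2.2e-05. Reads of close relatives could have been divided among Oas1a, Oas1g and their neighbours or among histone genes, so the size of those changes is uncertain.

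**Figure D2:**
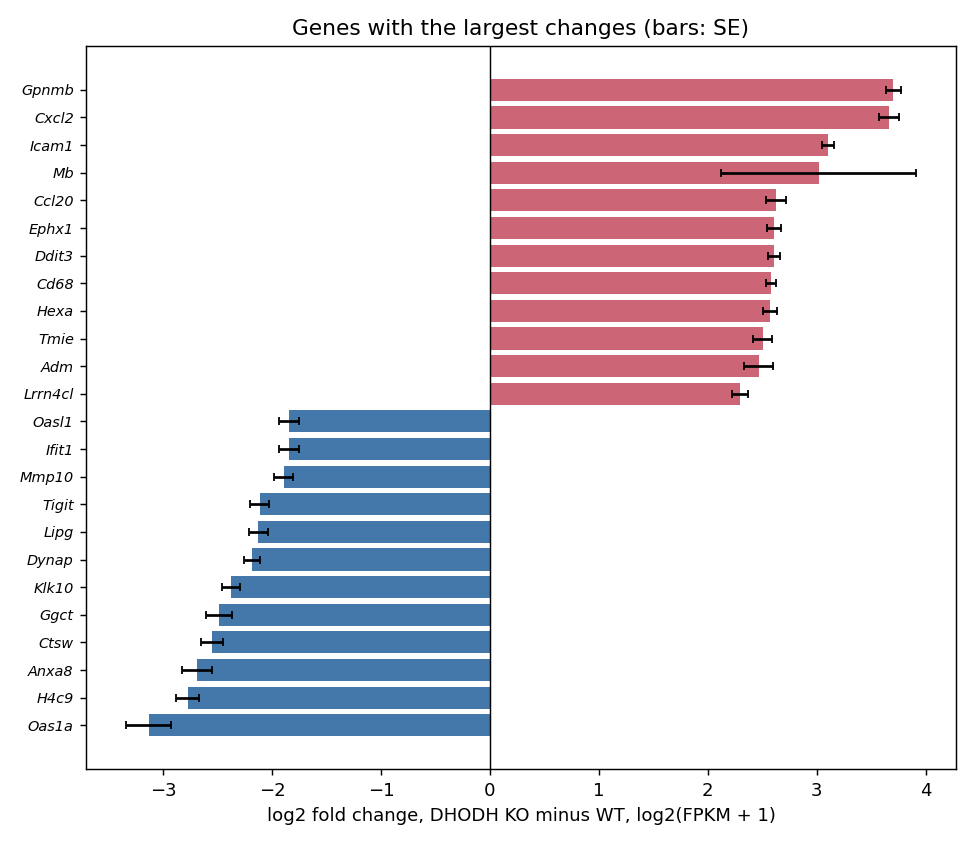
Log2 fold change (KO minus WT, log2(FPKM + 1)) of the 12 genes with the largest increases (red) and the 12 with the largest decreases (blue), with whiskers giving the SE from limma. Gpnmb had the largest increase at 3.70 and Oas1a the largest decrease at -3.13, and Mb had the widest SE at 0.895.

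In total 3618 genes were higher and 2958 lower in KO among 10170 genes tested, 64.7% of them. Most called changes were small, since 4402 of the 6576 called genes changed by less than 0.5 on the log2 scale. Asking for an absolute log2 fold change of at least 1 left 287 genes higher and 117 lower. Both KO values lay outside both WT values on the same side for 83.4% of the genes, where chance gives 33.3% for a single gene. Genes vary together, so any difference shared by the libraries of a genotype raises this share, whatever its source. DHODH KO replicate 2 held transcripts of genes that mark other tissues, as described at the end. Without it, the median log2 fold change over the genes tested was 0.032, against 0.039 with all libraries.

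Genes of pyrimidine synthesis and salvage went both ways in KO. On the list of de novo synthesis, 5 of 12 tested members fell and 1 rose (4 and 1 adjusted over the list alone). The targeted gene Dhodh is 1 of the 5 that fell. Cad, which encodes the enzyme of the initial steps of the pathway, fell from 64.6 ± 0.530 to 47.5 ± 0.790 FPKM (log2 fold change -0.44 ± 0.038, adjusted p = 6.7e-05). The nucleoside diphosphate kinase genes Nme1, Nme2 and Nme7 fell by 0.36, 0.23 and 0.32 on the log2 scale, and Nme3, picked after its value was seen, rose by 0.36 (0.195 without DHODH KO replicate 2). Of 14 tested members of pyrimidine salvage and nucleoside transport, 5 rose and 6 fell (the same adjusted over the list alone). Upp1, the uridine phosphorylase gene, fell from 17.5 ± 0.967 to 5.29 ± 0.523 FPKM (-1.56 ± 0.076, adjusted p = 6.1e-06), and the uridine-cytidine kinase gene Uck2 fell from 61.5 ± 0.356 to 39.0 ± 0.308 FPKM. The thymidine kinase gene Tk1 fell by 0.51, and Cmpk2, which is also an interferon-stimulated gene, fell by 2.13 on the log2 scale. The salvage genes that rose were Cda, Tk2, Dck, Uprt and Uck1, named after their values were seen, with log2 fold changes from 0.23 to 0.70, the lowest being Uck1 (0.127 without DHODH KO replicate 1). Neither list passed the test (adjusted p = 0.230 for synthesis and 0.301 for salvage).

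The list of pyrimidine breakdown was lower in KO, with 6 of 7 tested members down and none up, also when adjusted over the list alone (adjusted p = 0.0104, and adjusted p = 0.405 with an estimated correlation). Of the 11 genes listed, Dpyd, Dpys, Upb1 and Agxt2 lay below the expression filter. The result therefore does not cover them and rests on genes of enzymes that act on nucleotides. The ecto-nucleotidase gene Nt5e fell from 46.8 ± 0.278 to 19.2 ± 0.0215 FPKM (-1.25 ± 0.041, adjusted p = 1.5e-06). Nt5c, Samhd1 and Dctpp1, which encode enzymes that remove phosphates from nucleotides, fell by 0.64, 0.36 and 0.23 on the log2 scale. Deoxynucleotide supply was mixed, with 4 of 9 members down and 2 up, the same adjusted over the list alone, and did not pass (adjusted p = 0.221). Rrm2, the regulated subunit of ribonucleotide reductase, fell from 168 ± 3.10 to 85.1 ± 5.21 FPKM, and Mthfd1 and the thymidylate synthase gene Tyms fell by 0.82 and 0.47 on the log2 scale. Of the other nucleotide lists, purine synthesis had 3 of 15 members up and 7 down (adjusted over the list alone, 3 and 8, adjusted p = 0.209), and UDP-sugar and hexosamine synthesis had 5 of 17 up and 2 down (4 and 2 adjusted over the list alone, adjusted p = 0.796).

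Interferon-stimulated genes fell while genes of MHC class I antigen presentation rose. Of 36 tested type I interferon-stimulated genes, 30 fell and none rose (32 fell adjusted over the list alone), with a median log2 fold change of -0.91 (adjusted p = 1.7e-11, and adjusted p = 0.405 with an estimated correlation). Isg15, a ubiquitin-like protein gene, fell from 37.3 ± 1.52 to 12.9 ± 0.216 FPKM, Lgals3bp from 28.0 ± 1.203 to 10.3 ± 0.133 FPKM, and Oas1g from 4.19 ± 0.233 to 0.192 ± 0.0282 FPKM. Of 23 genes of MHC class I antigen presentation, 16 rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 0.80 (adjusted p = 0.00130, and adjusted p = 0.466 with an estimated correlation). The class I heavy chain genes H2-D1, H2-K1 and H2-Q4 rose 3.12-fold, 2.85-fold and 2.97-fold, to 628 ± 15.8, 206 ± 5.69 and 153 ± 0.644 FPKM, and the light chain gene B2m rose 2.75-fold to 1925 ± 90.2 FPKM. The class I genes are near copies of one another, so the division of reads among them is uncertain. The members that fell, named after their values were seen, were the chaperone gene Calr and the proteasome genes Psme1 and Psmb10.

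NF-kB targets and chemokines held more members up than down, without passing the test. Of 17 NF-kB feedback targets, 12 rose and 4 fell (adjusted p = 0.0560), Icam1 most. Of 22 tested chemokines and cytokines, 12 rose and 7 fell (adjusted p = 0.155), with Cxcl2 and Ccl20 among the risers. Both pairs of counts were the same adjusted over the list alone. The NF-kB list passed without WT replicate 1 (adjusted p = 0.0379), without DHODH KO replicate 1 (0.0395), with no filter (0.0244), median-ratio scaling (0.0401), quantile normalization (0.0286), ranks (0.0376), voom (0.0355) and fry (0.00268), over a range up to 0.428, the adjusted p with an estimated correlation.

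Mitotic genes fell together. Of 31 genes of G2/M and mitosis, 29 fell and none rose, also adjusted over the list alone, with a median log2 fold change of -0.63 (adjusted p = 1.7e-11, and adjusted p = 0.405 with an estimated correlation). The mitotic kinase genes Plk1 and Aurka fell from 102 ± 0.402 to 38.2 ± 0.709 FPKM and from 54.8 ± 0.459 to 22.4 ± 0.438 FPKM. The kinesin gene Kif20a fell by 1.11 and the spindle checkpoint gene Bub1b by 1.05 on the log2 scale, and the members not called were Bub1 and Ttk, named after their values were seen. G1/S and DNA replication did not move that way, with 19 of 36 members up and 7 down (adjusted p = 0.312), and the replication stress and DNA damage response list had 14 of 23 up and 5 down (adjusted p = 0.209). Ribosome biogenesis and RNA polymerase I genes fell, with 22 of 34 down and 2 up, Utp4 and Utp15 (adjusted p = 2.4e-04, and adjusted p = 0.405 with an estimated correlation). Npm1, the nucleolar chaperone gene, fell from 1618 ± 42.1 to 898.5 ± 10.99 FPKM, and the ribosomal RNA processing genes Rrp12 and Utp20 and the polymerase factor gene Taf1d fell by 0.82, 0.61 and 0.71 on the log2 scale. Cytosolic ribosomal proteins had 17 of 57 members up and 23 down (adjusted p = 0.168). All counts of these lists were the same adjusted over the list alone.

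Hypoxia targets rose almost throughout. Of 20 tested members, 19 rose and none fell, also adjusted over the list alone, with a median log2 fold change of 0.85, and Bnip3l was the member not called (adjusted p = 6.3e-07, and adjusted p = 0.405 with an estimated correlation). Ndrg1 rose from 118 ± 0.502 to 517 ± 13.8 FPKM, the angiogenic factor gene Vegfa from 6.76 ± 0.563 to 31.1 ± 0.261 FPKM, and the collagen prolyl hydroxylase genes P4ha1 and P4ha2 2.35-fold and 6.08-fold. Of 21 NRF2 targets, 16 rose and 4 fell (17 and 4 adjusted over the list alone, adjusted p = 0.00620, and adjusted p = 0.405 with an estimated correlation). The glutathione transferase gene Gstm1 rose from 4.85 ± 0.650 to 25.9 ± 1.03 FPKM, the quinone reductase gene Nqo1 from 14.1 ± 1.15 to 37.6 ± 0.133 FPKM, the malic enzyme gene Me1 2.01-fold, and Ftl1, the ferritin light chain gene, from 2326 ± 36.9 to 5172 ± 125 FPKM. Ftl1 and Gstm1 have near copies in the genome, so their levels are uncertain. Tkt, Abcc1, Taldo1 and G6pdx, most of them enzymes of the pentose phosphate pathway and named after their values were seen, were the NRF2 targets that fell.

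Immediate early genes, which also respond to the handling of cultures, rose, as did hypoxia and NRF2 targets. Of 17 tested, 13 rose and none fell, also adjusted over the list alone (adjusted p = 2.4e-04, and adjusted p = 0.405 with an estimated correlation), and Jun, Junb, Egr1 and Dusp1 rose 2.69-fold, 1.98-fold, 2.80-fold and 4.26-fold. The list of the endoplasmic reticulum unfolded protein response was lower, with 13 of 17 members down and 3 up (adjusted p = 0.00707, and adjusted p = 0.405 with an estimated correlation). Pdia6, Hsp90b1 and Calr fell by 0.59, 0.45 and 0.45 on the log2 scale, whereas Dnajb9 rose from 7.57 ± 0.609 to 15.7 ± 0.303 FPKM, beside Herpud1 and Edem1, and Hspa5 was not called (adjusted p = 0.105), these last 3 named after their values were seen. Of 35 tested ATF4 targets of the integrated stress response, 21 rose and 12 fell, with Ddit3 the largest increase (adjusted p = 0.107). The p53 targets had 10 of 20 up and 3 down (adjusted p = 0.0898), heat shock genes 7 of 10 up and 1 down (adjusted p = 0.0898), ferroptosis regulators 7 of 18 up and 7 down (adjusted p = 0.946), and mitochondrial stress proteins 3 of 12 up and 6 down (adjusted p = 0.392). The ferroptosis list had a median of -0.03 and a mean of 0.12, and the mitochondrial stress list a median of -0.11 and a mean of 0.02. Counts of these lists were the same adjusted over the list alone.

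Most tested genes on the lists of the TCA cycle and of fatty acid synthesis fell. Pathways of the authors' annotation for these processes, tested after the data were seen, did not pass, as described at the end. Of 23 TCA cycle genes, 16 fell and 3, Dlat, Idh3a and Idh3b, rose (adjusted p = 0.00474, and adjusted p = 0.483 with an estimated correlation). The oxoglutarate dehydrogenase gene Ogdh fell from 25.7 ± 0.829 to 12.02 ± 0.488 FPKM, the citrate synthase gene Cs from 139 ± 0.420 to 91.2 ± 2.96 FPKM, and Got1 and Dlst by 0.77 and 0.58 on the log2 scale. Of 17 tested genes of fatty acid synthesis and desaturation, 13 fell and 3 rose (adjusted p = 0.00347, and adjusted p = 0.405 with an estimated correlation). The desaturase genes Scd2 and Fads2 fell from 174 ± 0.962 to 93.2 ± 0.404 FPKM and from 58.4 ± 1.64 to 27.8 ± 1.18 FPKM, and Fasn and Acaca, which encode the enzymes that build fatty acids, fell by 0.66 and 1.06 on the log2 scale. The members that rose were Dgat1 and Dgat2, enzyme genes of triglyceride synthesis, and Elovl5, named like Dlat, Idh3a and Idh3b after their values were seen. Cholesterol synthesis had 8 of 24 members up and 13 down (adjusted p = 0.0788), and glycolysis 12 of 22 up and 4 down (adjusted p = 0.112). The nuclear genes of the respiratory chain and ATP synthase had 23 of 72 up and 21 down (adjusted p = 0.796), with a median of 0.03 while the test leaned downward, and electron donors to ubiquinone with ubiquinone synthesis 10 of 21 up and 8 down (adjusted p = 0.796). Counts of these lists were the same adjusted over the list alone. Mitochondrially encoded genes were not analysed here.

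**Figure D3:**
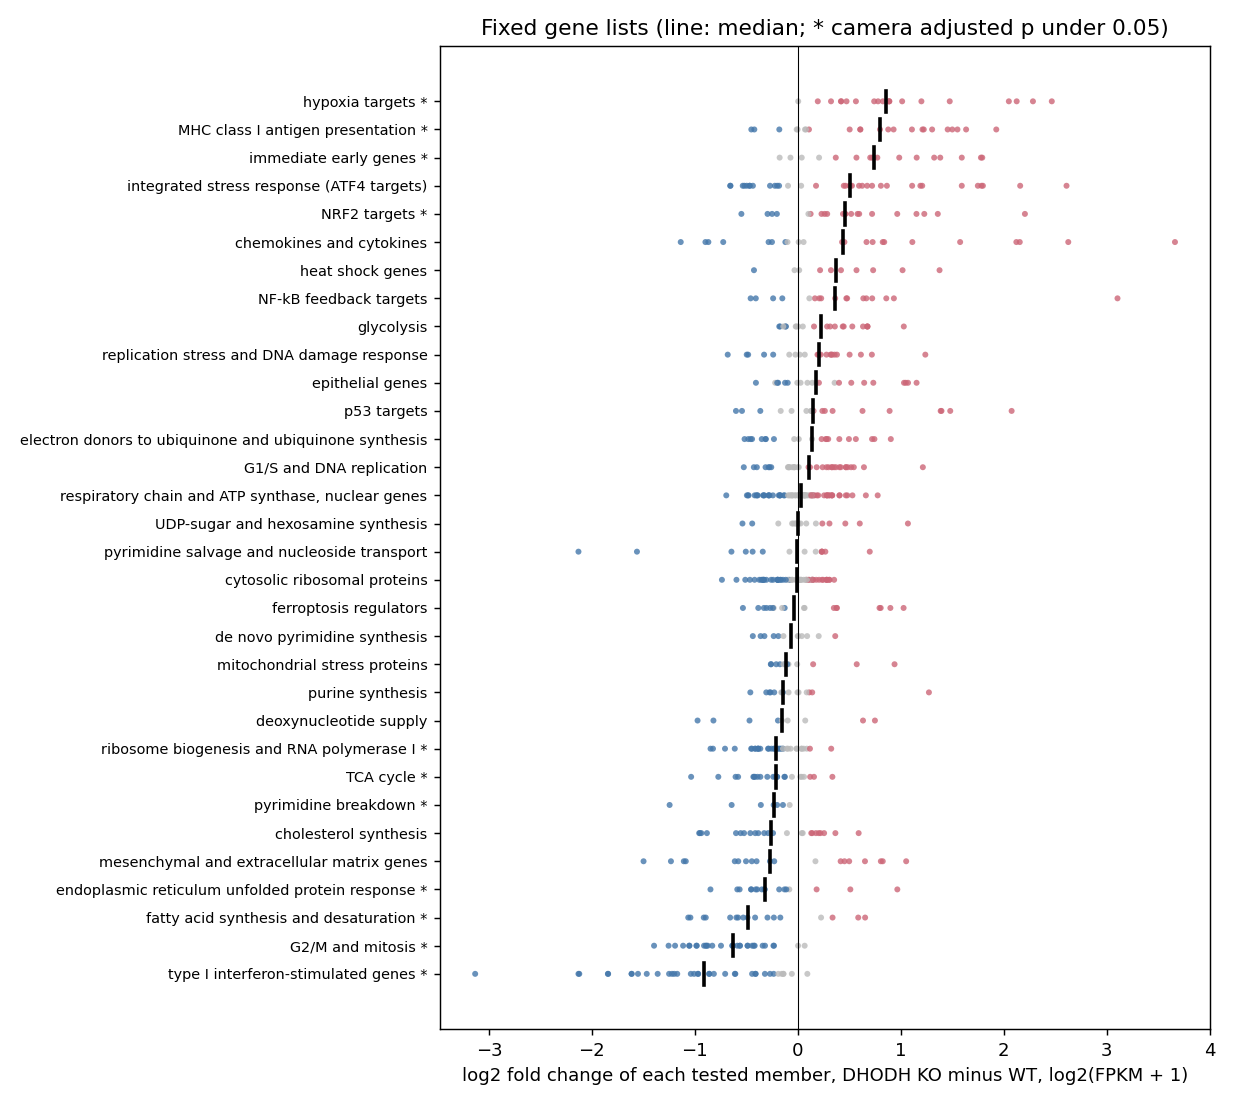
Log2 fold change (KO minus WT, log2(FPKM + 1)) of every tested member of the 32 lists tested, as red points where the gene was called higher, blue where lower and grey where not called, with the list median as a black line and a star for the 11 lists with a camera adjusted p under 0.05. The medians of the interferon-stimulated genes (-0.91) and of G2/M (-0.63) lie lowest and those of hypoxia targets (0.85) and MHC class I (0.80) highest.

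Epithelial genes had 9 of 21 tested members up and 5 down (adjusted p = 0.155), and mesenchymal and extracellular matrix genes 7 of 19 up and 11 down (adjusted p = 0.218), the same adjusted over the list alone. Of 14 measured markers of immune cells, 3 lay above the expression filter. Cd68 and S100a8 rose and Cd14 fell, the latter pair named after their values were seen, whereas Ptprc stayed at or below 0.0393 FPKM in each library. Among fibroblast and endothelial markers, Pdgfra alone passed the filter and was not called (log2 fold change -0.16 ± 0.083, adjusted p = 0.130). Several other members of that list were higher in DHODH KO replicate 2 than in each other library, among them Col3a1 at 2.95 FPKM against at most 0.0356 FPKM, picked after its values were seen.

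DHODH KO replicate 2 also carried transcripts of marker genes of heart muscle and blood. Actc1, the cardiac actin gene, measured 32.9 FPKM there and was listed at 0 in the other 3 libraries, as were the myosin light chain genes Myl3 and Myl2 at 19.9 and 11.6 FPKM. The haemoglobin gene Hbb-bs measured 8.47 FPKM there and at most 0.497 FPKM elsewhere. These genes were chosen after their values were seen. Of the 3618 genes higher in KO, 5 had a value in DHODH KO replicate 2 over 2 times that in DHODH KO replicate 1. Genes whose KO libraries differ widely are less likely to be called, so this count was bound to be small. It does not show how far such transcripts reach into the other genes.

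**Figure D4:**
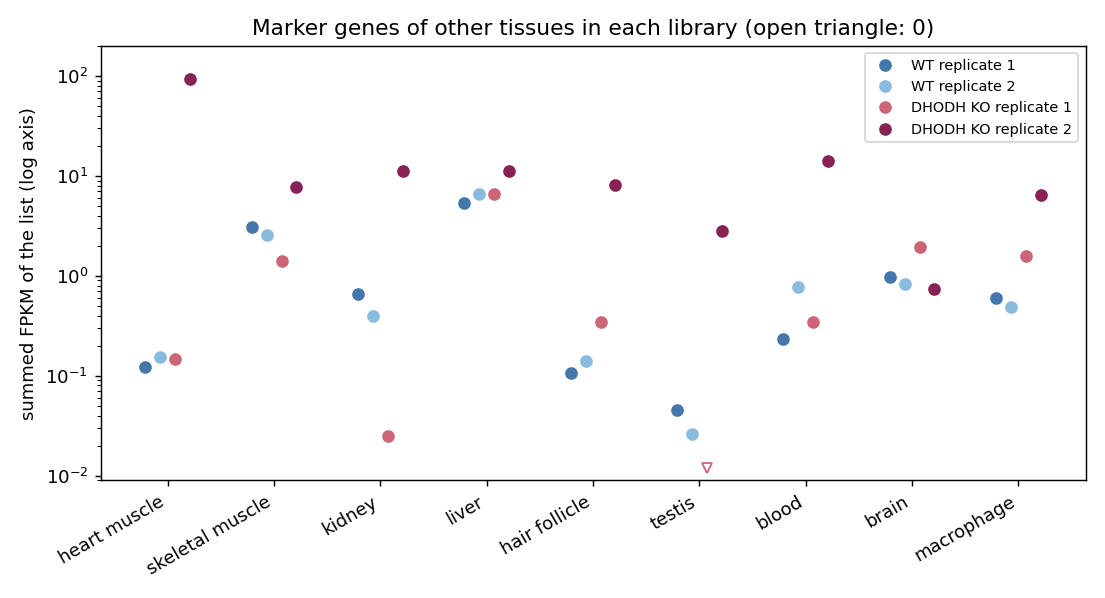
Summed FPKM (log axis) of marker genes of 8 tissues and of macrophages in each library, leaving out genes at 1 FPKM or more in every library, with an open triangle for a sum of 0. DHODH KO replicate 2 lies at 93.9 FPKM for heart muscle, where the other libraries lie at or below 0.153 FPKM.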

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

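The tests on DHODH KO replicate 2 given here, and the tissue marker lists behind them, were chosen after the values had been seen. DHODH KO replicate 2 held 892 genes above 0 that were listed at 0 in the other 3 libraries, against 334 in WT replicate 1, 274 in WT replicate 2 and 261 in DHODH KO replicate 1. In it, 48 genes exceeded 1 FPKM while staying under 0.5 FPKM in each other library, against 5, 2 and 2 such genes in the others. Such a gene entered the comparison of genotypes only where its mean over the 4 libraries reached 1 FPKM.

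Greater depth is argued against, since the depth of DHODH KO replicate 2 was 1.001 times that of DHODH KO replicate 1. Reads from other mouse tissues are a candidate source, as 5 of 8 tissue lists summed to at least 10 times their highest sum in the other libraries. Those were heart muscle (93.9 FPKM, 615 times), testis (2.83, 62.5 times), hair follicle (8.03, 23.4 times), blood (14, 18.1 times) and kidney (11.2, 17.1 times), while skeletal muscle (7.74, 2.51 times), liver (11.1, 1.68 times) and brain (0.733, 0.381 times) stayed under that bound. Kidney passed the bound only with Kap. Without the highest gene of each list in DHODH KO replicate 2, kidney stood at 3.37 times, while heart muscle stood at 399.5 times, testis at 39.7 times, blood at 19.95 times and hair follicle at 19.0 times. Kap was not the only kidney gene seen there alone. Umod, Klk1, Slc34a1, Cyp4b1, Miox and Slc22a6 lay at 0.0329 to 0.550 FPKM and were listed at 0 in each other library. Napsa went the other way, at 0.179 FPKM there against 0.612 FPKM in WT replicate 1. Whether such reads came from RNA, from the library or from assignment of reads during sequencing stays open. No biological explanation was tested, since these genes were picked for being at 0 in DHODH KO replicate 1.

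Genes at 1 FPKM or more in every library were left out of those sums, 2 of 16 measured for heart muscle, 1 of 12 for skeletal muscle, 0 of 11 for kidney, 7 of 15 for liver, 0 of 12 for hair follicle, 1 of 8 for testis, 0 of 6 for blood and 1 of 9 for brain. In DHODH KO replicate 2 the highest gene of the heart muscle list was Actc1 at 32.9 FPKM, of the kidney list Kap at 8.99 FPKM and of the blood list Hbb-bs at 8.47 FPKM.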

How the results depend on the processing

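The voom setting was added after seeing the data. Counts of called genes stayed within 1.5 times the reported ones in every alternative but the fold threshold, and no gene was called in opposite directions. An absolute log2 fold change of at least 1 left 287 genes higher and 117 lower by its construction. Without each library in turn, 3165 to 3391 genes were higher, 2490 to 2863 lower, 11 to 13 lists passed, and the log2 fold change of Dhodh ran from -0.26 to -0.12; the lone sample was assumed to vary like the other group. For Dhodh the call was lost with no filter and without the trend (both -0.189), after TPM rescaling (-0.191), with voom (-0.209) and with the fold threshold (-0.189). Median-ratio scaling gave 3252 higher and 3279 lower and quantile normalization 3117 and 3392, with the median over all genes going from 0.04 to 0.00 and -0.01. With the correlation estimated, 0 lists passed, and with fry, which does not compare a list with other genes, 26; the 11 lists passed in all other settings. With the replicate block, 3681 genes were higher, 3001 lower and 11 lists passed; deviations of same-numbered samples correlated at 0.046, with too few pairs to treat the numbers as a pairing. The cause was not tested for these or for the medians of uncalled lists that changed sign. These were, with no filter, ferroptosis (0.0340) and mesenchymal genes (0.0246); with a mean of at least 5 FPKM, pyrimidine salvage (0.148); with median-ratio scaling, UDP-sugar synthesis (-0.0316) and the respiratory chain (-0.0108); with quantile normalization, UDP-sugar synthesis (-0.0253) and ribosomal proteins (0.0123); with voom, ribosomal proteins (0.00630). Without each library in turn, the medians ran from -0.153 to 0.0114 for de novo synthesis, -0.0336 to 0.0182 for salvage, -0.0594 to 0.00278 for ferroptosis and -0.0653 to 0.0178 for ribosomal proteins, the higher ends coming without WT replicate 2 for synthesis and without DHODH KO replicate 1 for the rest. Lists not called otherwise passed, besides NF-kB targets, with no filter (ATF4 targets 0.0453, p53 targets 0.0388), quantile normalization (ATF4 targets 0.0402, glycolysis 0.0362, heat shock 0.0193), voom (heat shock 0.00201), without WT replicate 1 (cholesterol synthesis 0.0294) and without WT replicate 2 (ATF4 targets 0.0452), these being adjusted p-values. The tests meant for tables of counts were not run.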

Other observations

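The pathway test and the tests of macrophages and of scaling for the lysosomal genes were chosen after the genes concerned had been seen. Camera over 302 pathways of the authors' annotation gave 14 higher and 4 lower in KO, of which 0 passed with an estimated correlation (adjusted p = 0.869 for each of the 18). Those lower were the spliceosome, with 65 of 125 genes down and 22 up (adjusted p = 0.00368), ribosome biogenesis in eukaryotes, with 34 of 70 down and 10 up (0.0105), RNA transport, with 65 of 147 down and 24 up (0.0110), and cytosolic DNA sensing, with 24 of 42 down and 8 up (0.0312). Among those higher, cell adhesion molecules had 34 of 51 genes up and 6 down (0.00271) and glycosaminoglycan degradation 11 of 15 up and 1 down (0.0105), and all 15 genes of the latter also belong to the lysosome pathway. Allograft rejection had 14 of 17 up and 1 down (0.00202), and it and cell adhesion molecules each hold 7 genes of the MHC class I list. Autoimmune thyroid disease, graft-versus-host disease, type I diabetes mellitus, natural killer cell mediated cytotoxicity and viral myocarditis, also higher, hold 7 each. Antigen processing and presentation had 26 of 44 up and 7 down (0.0356) and holds 16, and the phagosome holds 11. Many of the 14 thus share genes and are not separate findings. Pathways close to the metabolic lists did not pass. Pyrimidine metabolism had 21 of 42 down and 8 up (0.0785), and the citrate cycle 17 of 28 down and 5 up (0.0756). Fatty acid biosynthesis had 5 of 14 down and 2 up (0.553). Biosynthesis of unsaturated fatty acids had 9 of 21 down and 7 up, with a median of 0.134 (0.933). Larger pathways near the hypoxia, unfolded protein and mitotic lists did not pass either. HIF-1 signaling had 32 of 83 up and 20 down (0.596). Protein processing in endoplasmic reticulum had 52 of 148 down and 45 up (0.636), and cell cycle 33 of 116 down and 35 up (0.811).

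Lysosomal genes were higher in KO, with 71 of 104 genes of the pathway up and 10 down, a median log2 fold change of 0.31 and an adjusted p of 4.8e-05 over the pathways (adjusted p = 0.869 with an estimated correlation). Chosen after their values were seen, the lysosomal protease gene Ctsd rose from 149 ± 3.05 to 332 ± 1.93 FPKM. The membrane protein genes Lamp1 and Lamp2 rose from 388 ± 0.355 to 613 ± 4.84 FPKM and from 31.9 ± 0.493 to 64.0 ± 1.18 FPKM, and the proton pump genes Atp6v0b and Atp6v0c rose by 1.41 and 0.94 on the log2 scale.

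Macrophages in the KO cultures are argued against as a source of these genes, since the median of 15 macrophage genes reached at most 0.151 FPKM in a KO library, where Cd68 stood at 89.5 FPKM in DHODH KO replicate 1 and 91.7 FPKM in DHODH KO replicate 2. The highest of the 15 were Aif1 at 0.725 FPKM in the former and Lyz2 at 3.51 FPKM in the latter, and their sum was 1.58 and 6.41 FPKM. None of the 15 genes reached 1 FPKM in every library. Median-ratio scaling and quantile normalization brought the median of all genes from 0.0389 to 0.00196 and -0.0129. The pathway median stayed at 0.271 and 0.286, with 66 genes up under each and 11 and 12 down. So small a shift of all genes could not remove the rise, so this outcome was fixed in advance. The values show only that scaling differences of the size corrected do not account for the whole rise. Larger differences were not tried. Gene length and expression level are argued against as well, since 99% of 10000 matched random lists had medians between -0.0863 and 0.164. That the pathway median lay at percentile 100 of them is no further support for the rise. The pathway was taken up for its rise in these data, and random lists drawn gene by gene hold no correlation between genes. Loss of DHODH and other differences between the KO and WT cells stay open as the source of the rise and were not tested, since the labels do not say how many KO lines were used.

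The opposite movement of interferon-stimulated and MHC class I genes was weighed in the same way. Under quantile normalization the class I median was 0.782 and that of interferon-stimulated genes -1.01. Median-ratio scaling and quantile normalization moved the median of all genes only from 0.0389 to 0.00196 and -0.0129. Neither list median could change sign under so small a shift, so keeping the sign was fixed in advance. The values show only that scaling differences of the size corrected do not account for the opposite movement. Gene length and expression level are argued against, because the class I median exceeded the interferon median by 1.75 among genes with a known length, where 99% of 10000 pairs of matched random lists lay between -0.366 and 0.313. The 2 lists were paired for their opposite movement in these data, so lying outside that range is no further support for it. Loss of DHODH and other differences between the KO and WT cells stay open as the source of either change, and what raised the class I genes was not tested.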
